A study of Mus musculus with 6 samples.

How the data were processed

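Total RNA from frozen right kidneys of 3 Far2 knockout and 3 wild-type male mice was sequenced from stranded libraries with ribosomal RNA removed, per the labels' protocols. The submitters' processing notes name cutadapt 1.2.1, TopHat2 2.0.13, Bowtie2 2.2.3, SAMtools 1.2, Cufflinks 2.2.1, Cuffdiff and the mm10 assembly, with no role or order. The gene models, the strand setting and the treatment of fragments with several alignments are not given in the sources used here. Genes that overlap, or that share fragments with a near-identical copy, are therefore uncertain.

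The authors deposited an estimated count of fragments for each gene and library. It is whole except in 312 genes, where 1.12% of all values fall between whole numbers (exact match required). The authors also deposited FPKM for each library, scaled between libraries by Cuffdiff, and the mean FPKM of each group. Per the file headers, the authors' comparison table gives a log2 fold change of knockout over wild type, a p-value and a q-value for each gene. A table of scaled group means was not used here.

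The numbers 0, 1 and 2 that the deposited table gives the libraries of a group match no sample label, so a library stands for 1 mouse of its group and for no named mouse. The labels describe the samples as biological replicates. Libraries of one group differed by 5.99 to 23.3 times the variance of counting, which is more than a repeated read-out of 1 library would give. The table holds 23396 genes, of which 4637 are at 0 in all libraries. The libraries held from 15261362 to 20631158 fragments. Counting error is small at this depth for abundant genes and large for genes with few fragments, such as Far2.

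The estimated counts were rounded to whole numbers. Genes were filtered with filterByExpr, scaled by TMM and tested with edgeR 4.0.16 (quasi-likelihood F test, 2 groups, no covariates, two-sided) in R 4.3.3. The threshold was a Benjamini-Hochberg adjusted p under 0.05. CPM values were computed on library sizes scaled by TMM. Gene lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 40 lists of 5 or more tested members. In total 41 lists of pathways, RNA quality and cell types had been written before the data were examined. Beside it stand camera with an estimated correlation and fry, which tests whether the genes of a list move on balance one way. Genes near Far2 were counted by their locus in the deposited table.

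The rule for named genes was fixed before the data were examined. It takes Far2, then up to 10 genes per direction past the threshold with the largest change, an average log2 CPM of 0 or more and no overlap between groups, leaving out Gm numbers, Rik clones, accessions, Mir and Snor genes and merged names. Where fewer than 5 pass in a direction, genes with the smallest p are added to make 5 and are given as values. It then takes up to 3 called members of each list, or the 1 member with the smallest p, and any called gene within 2 Mb of Far2. Other genes in the text were chosen after their values were seen. Results for some single genes are not reported here.

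Alternatives were RLE and upper-quartile scaling, no filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, limma on log2(FPKM + 1) and log2(FPKM + 0.1), robust dispersion, thresholds of 0.01 and 0.10, a test against a fold of 1.2, removal of mitochondrial and small noncoding genes, windows of 1 and 5 Mb around Far2, and leaving out each library in turn. After the data were seen, DESeq2 with each library left out, chiefly wild-type library 0, limma-voom with library quality weights, and camera after a smooth trend on transcript length and GC was taken out were added. Length and GC came from the longest GENCODE transcript of each gene and were found for 99.0% of tested genes. Summaries were made in Python 3.11.15.

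The test was tried on simulated counts with the means, library sizes and spread of these libraries. With 200 of 14354 genes changed, edgeR recovered 53.8% of 1.5-fold, 80.3% of 2-fold and 96.5% of 4-fold changes in the simulated comparison of knockout with wild type. False calls made up 7.3% to 10.1% of the calls by edgeR and 9.2% to 11.8% of those by DESeq2. For simulated lists of 20 genes, camera found 20 of 20 lists shifted by 0.3 on the log2 scale and 0 of 20 lists not shifted. The simulated genes varied independently of each other, and no simulated library was set apart across many genes. The simulation therefore does not gauge false calls for lists whose genes vary together. The shares recovered may not hold for the real comparison, and list shifts smaller than 0.3 were not tried.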

Results

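RNA from the right kidneys of 6 male mice aged 6 months was sequenced after removal of ribosomal RNA. Of these mice, 3 were homozygous for a targeted Far2 allele (knockout) and 3 were C57BL/6N wild type. Far2 encodes fatty acyl-CoA reductase 2, an enzyme that reduces fatty acyl-CoA to fatty alcohol, a precursor of wax esters and ether lipids. The deposited table numbers the libraries of each group 0, 1 and 2. The wild-type libraries held 19668174, 20631158 and 15843181 fragments assigned to genes, and the knockout libraries 17611810, 15261362 and 18650250. After genes with low counts were removed, 14354 genes were tested. The biological coefficient of variation between mice of a group was 10.1%.

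The comparison asks how the kidney transcriptome of Far2 knockout mice differs from that of wild-type mice. No single gene passed edgeR's quasi-likelihood test after Benjamini-Hochberg adjustment (1193 had an unadjusted p under 0.05), and DESeq2 called 12. A split of the libraries that mixes the genotypes gave 105 calls by DESeq2. Pdk4, a kinase that inhibits pyruvate dehydrogenase, averaged 53.2 ± 3.96 CPM (SD, n = 3) in knockout and 31.2 ± 2.06 CPM in wild type. Cyp27b1, the renal enzyme that makes active vitamin D, averaged 5.01 ± 1.41 CPM in knockout and 13.3 ± 2.95 CPM in wild type. As groups, nuclear genes of oxidative phosphorylation and genes of cholesterol synthesis, fatty acid oxidation and ether lipid metabolism were higher in knockout, by small steps. Genes of the extracellular matrix, mesangial cells and vascular smooth muscle were lower as groups. These group calls came from camera with a preset correlation, and none held with an estimated correlation (adjusted p = 0.400 for oxidative phosphorylation and mesangial cells and 0.293 for the other 5 lists) or by fry.

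Far2 itself was near the lower limit of measurement in both groups. The library totals were 40, 40 and 22 fragments in wild type and 28, 19 and 31 in knockout. Its mean was 1.77 ± 0.30 CPM (SD, n = 3) in wild type and 1.51 ± 0.22 CPM in knockout. The log2 fold change was −0.23 with a standard error of 0.24, and the ranges of the groups overlapped (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.781). The 95% confidence interval, −0.78 to 0.31, corresponds to a knockout level of 0.583 to 1.24 times the wild-type level. In the GENCODE annotation of GRCm38, the assembly that mm10 names, Far2 (ENSMUSG00000030303.15) lies on the plus strand of chromosome 6 from 148047259 to 148182758. It has 3 annotated transcripts, the longest with 13 exons. The deposited values count fragments over the whole gene and do not show which exons they came from. They therefore do not check the genotype labels, which were taken as given. In the deposited table Far2 shares a locus, from 148047416 to 148444352, with Ergic2, Tmtc1 and Rps4y2. Of the 26 tested genes within 2 Mb of Far2, 0 passed edgeR's quasi-likelihood test after Benjamini-Hochberg adjustment, 0 passed DESeq2, and 2, Med21 and Rps4y2, had an unadjusted p under 0.05.

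Among the genes with an average log2 CPM of 0 or more that were higher in all 3 knockout libraries than in any wild-type library, those with the smallest p were Pdk4, Zfp810, Xbp1, Mvk and Ints2. Their log2 fold changes were 0.77 ± 0.085 (SE) for Pdk4, 0.65 ± 0.098 for Zfp810, 0.38 ± 0.066 for Xbp1, 0.45 ± 0.095 for Mvk and 0.28 ± 0.062 for Ints2. The deposited locus of Zfp810 overlaps that of another gene, so its count is less certain, and its q in the authors' Cuffdiff comparison was 0.485. Xbp1 is a transcription factor of the unfolded protein response, and Mvk encodes mevalonate kinase of the cholesterol pathway. Mvk was tightly grouped, at 8.43 ± 0.058 CPM in wild type and 11.5 ± 0.27 CPM in knockout. Among the genes that were lower in all 3 knockout libraries, those with the smallest p were Cyp27b1, Aldh1a3, Mbp, Loxl2 and Thsd4. Cyp27b1 had a log2 fold change of −1.40 ± 0.22 (SE), a level 2.65-fold lower in knockout. The values were −0.59 ± 0.11 for Aldh1a3, which makes retinoic acid, −0.51 ± 0.095 for Mbp, −0.54 ± 0.11 for Loxl2, a collagen cross-linking oxidase, and −0.52 ± 0.11 for Thsd4. The smallest adjusted p of any gene was that of Pdk4, 0.0722 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

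At an adjusted p under 0.05 edgeR's quasi-likelihood test called 0 of the 14354 genes, and 1193 genes had an unadjusted p under 0.05 where chance gives 717.7. Of the 1193, 455 were higher and 738 lower in knockout. This count was 516 without knockout library 1 and between 889 and 1615 without each other library, and a split of the libraries that mixes the genotypes gave 1594. The groups did not overlap for 2021 genes, 14.1% of those tested, where chance gives 10%. DESeq2 called 12 genes after Benjamini-Hochberg adjustment, 8 higher and 4 lower. The 8 were Pdk4, Zfp810, Scd1, Xbp1, Ttr, Capn11, Gm12070 and 8430408G22Rik, and the 4 were Cyp27b1, Tgfbi, mt-Rnr1 and 9530091C08Rik. Scd1, which desaturates fatty acids, averaged 210.2 ± 36.9 CPM (SD, n = 3) in knockout and 142 ± 17.7 CPM in wild type. Tgfbi, a matrix protein, averaged 11.6 ± 2.94 CPM in knockout and 20.1 ± 4.35 CPM in wild type. With 1 library left out DESeq2 called from 5 genes, without knockout library 1, to 47 genes, 10 higher and 37 lower, without wild-type library 0. The counts were 16 without wild-type library 1, 34 without wild-type library 2, 17 without knockout library 0 and 18 without knockout library 2. The DESeq2 fits with a library left out were chosen after seeing the data. With all 6 libraries, a split that mixes the genotypes gave 105 calls by DESeq2, more than the real split.

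**Figure D1:**
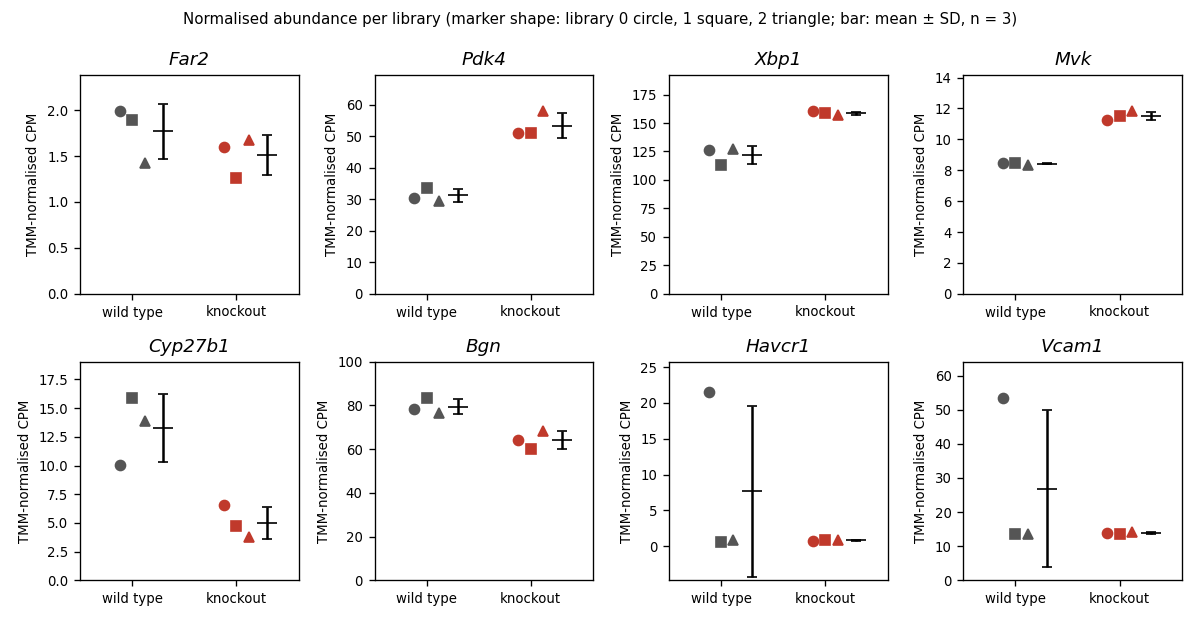
Normalised abundance (CPM) of 8 genes in each of the 6 libraries, grey for wild type and red for knockout, with bars for the mean and SD of 3 libraries. The groups separate for Pdk4, Xbp1, Mvk, Cyp27b1 and Bgn and overlap for Far2, while Havcr1 and Vcam1 are high in wild-type library 0 only, at 21.5 and 53.4 CPM.

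Gene lists fixed before the data were examined were compared with all other genes by camera. Of 40 lists, 20 passed with its preset correlation between genes, 12 higher and 8 lower in knockout, and 7 of the 20 passed with each library left out in turn. Splits of the libraries that mix the genotypes passed from 6 to 21 lists. With a correlation estimated from these libraries, 0 of the 40 passed and the smallest Benjamini-Hochberg adjusted p was 0.293. No member of any list passed edgeR's quasi-likelihood test over all genes tested, while DESeq2 called the members Pdk4, Scd1, Cyp27b1 and Tgfbi. Members below are given as values, and those past the threshold when adjusted over a list alone are so by edgeR. Genes of a list can vary together, so counts of members in one direction are not independent results. The estimated correlation between genes was 0.30 for oxidative phosphorylation, 0.26 for mesangial cells and 0.70 for macrophages.

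All 41 genes of the mitochondrial oxidative phosphorylation list, all encoded in the nucleus, had a higher mean in knockout, 25 of them without overlap between groups. Of all 14354 genes tested, 1022 were higher in knockout without overlap. The median log2 fold change of the list was 0.12 (camera adjusted p = 4.48e-10; adjusted p = 0.400 with an estimated correlation). The protein genes of the mitochondrial genome, not in the list, took 9.38 ± 0.63% of fragments (SD, n = 3) in wild type and 9.33 ± 0.20% in knockout. Ndufb8, a complex I subunit, averaged 201.3 CPM in wild type and 237 CPM in knockout, and Cox6c, of cytochrome c oxidase, 249.7 and 269 CPM. None of the 41 passed when adjusted over the list alone. Cholesterol synthesis genes were higher for 21 of 25 members, with a median of 0.24 (camera adjusted p = 9.06e-08; adjusted p = 0.293 with an estimated correlation). Examples are Mvk, the only member past the threshold when adjusted over the list alone, Idi1 with a log2 fold change of 0.59 ± 0.18 (SE) and Sqle with 0.26 ± 0.075.

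Fatty acid oxidation and PPAR alpha target genes were higher for 28 of 30 members, with a median of 0.14 (camera adjusted p = 1.96e-06; adjusted p = 0.293 with an estimated correlation). Pdk4 alone passed when adjusted over the list alone, and Plin2, a lipid droplet protein, had a log2 fold change of 0.23 ± 0.10 (SE). All 16 tested genes of the ether lipid and wax ester synthesis list were higher in the mean, with a median of 0.14 (camera adjusted p = 8.36e-05; adjusted p = 0.293 with an estimated correlation). The list as written also holds enzymes that break these lipids down, such as Agmo and Tmem86b. Dhrs7b, the reductase of ether lipid synthesis, stood at 0.25 ± 0.083 and Far1, the paralog of Far2, at 0.17 ± 0.13, and 0 of the 16 passed when adjusted over the list alone. Fatty acid synthesis genes were higher for 15 of 18 members, with a median of 0.13 (camera adjusted p = 0.00186; adjusted p = 0.293 with an estimated correlation), and Scd1 passed when adjusted over the list alone. Without wild-type library 0 the fatty acid synthesis list had a median of 0.15 and a camera adjusted p of 0.0662, and without knockout library 2 a median of 0.085 (adjusted p = 0.0319). Peroxisome genes were higher for 19 of 26 members, with a median of 0.064 (camera adjusted p = 0.0319; adjusted p = 0.303 with an estimated correlation), and this call was lost without wild-type library 0 or 1 or knockout library 1 or 2 (adjusted p = 0.0531 to 0.120). With the length and GC trend taken out, an alternative chosen after seeing the data, the peroxisome median was 0.086 and the camera adjusted p 0.0507.

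Extracellular matrix and fibrosis genes were lower in knockout for 36 of 41 members, with a median log2 fold change of −0.24 (camera adjusted p = 1.96e-06; adjusted p = 0.293 with an estimated correlation). Bgn, a proteoglycan, averaged 79.4 ± 3.54 CPM (SD, n = 3) in wild type and 64.1 ± 4.17 CPM in knockout, and Fn1, fibronectin, 33.4 ± 6.05 and 24.4 ± 4.30 CPM. Bgn and Tgfbi passed when adjusted over the list alone. With the length and GC trend taken out, chosen after seeing the data, the matrix median on log2 CPM went from −0.23 to −0.13 (camera adjusted p = 0.000414). The basement membrane collagens Col4a1 and Col4a2 were close to equal, with log2 fold changes of −0.057 ± 0.070 (SE) and −0.066 ± 0.073. All 16 mesangial cell and pericyte genes had a lower mean in knockout, with a median of −0.25 (camera adjusted p = 3.93e-05; adjusted p = 0.400 with an estimated correlation). They include Rgs5 at −0.34 ± 0.080, which passed when adjusted over the list alone, Pdgfrb at −0.25 ± 0.096 and Itga8 at −0.23 ± 0.077. All 12 vascular smooth muscle genes were lower in the mean, with a median of −0.23 (camera adjusted p = 0.00186; adjusted p = 0.293 with an estimated correlation), for example Synpo2 at −0.44 ± 0.13 and Myh11 at −0.37 ± 0.15. Without wild-type library 1 the smooth muscle median was −0.12 (camera adjusted p = 0.0257), and on log2(FPKM + 1) it was −0.10 (adjusted p = 0.00471). Podocyte genes were lower for 13 of 15 members, with a median of −0.16 (camera adjusted p = 0.0158; adjusted p = 0.574 with an estimated correlation), although Nphs1, which encodes nephrin, stood at −0.082 ± 0.15. The podocyte call was lost without wild-type library 1 (median −0.078, camera adjusted p = 0.197) or knockout library 1 (−0.070, adjusted p = 0.115), where the median shrank, and without knockout library 2 (−0.17, adjusted p = 0.0540), where it did not. Without knockout library 0 the podocyte median was −0.26, and with the length and GC trend taken out it went from −0.18 on log2 CPM to −0.091 (camera adjusted p = 0.0168).

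Wild-type library 0 stood apart in genes of tubular injury, inflammation and stroma. Havcr1, the injury marker KIM-1, was at 21.5 CPM there, at 0.617 and 0.844 CPM in the other wild-type libraries and at 0.740 to 0.916 CPM in knockout. Lcn2 was at 9.38 CPM against 1.61 and 1.30 in the other wild-type libraries, C3 at 112 CPM against 16.1 and 17.8, Vcam1 at 53.4 CPM against 13.7 and 13.6, and Lyz2 at 83.7 CPM against 14.0 and 14.1. All 17 macrophage genes had a lower mean in knockout, with a median of −0.45 (camera adjusted p = 0.00186; adjusted p = 0.584 with an estimated correlation), and without wild-type library 0 the median was 0.038 (adjusted p = 0.631; 0.0906 without knockout library 0). Fibroblast genes were lower for 11 of 13 members, with a median of −0.43 (camera adjusted p = 0.00186; adjusted p = 0.574 with an estimated correlation), and the median was −0.086 without that library (adjusted p = 0.119). Proliferation genes were lower for 22 of 26 members, with a median of −0.22 (camera adjusted p = 0.00605; adjusted p = 0.574 with an estimated correlation), and the median was −0.093 without it (adjusted p = 0.538; 0.126 without knockout library 0). The 6 tested T and NK cell genes had a median of −0.78 (camera adjusted p = 0.0319; adjusted p = 0.584 with an estimated correlation), a call that was lost without wild-type library 0 or 2 or knockout library 0 (medians −0.37, −0.68 and −0.21; adjusted p = 0.340, 0.283 and 0.963). Tubular injury genes did not pass, with a median of −0.22 (camera adjusted p = 0.153), and the median was 0.053 without wild-type library 0. With the length and GC trend taken out, chosen after seeing the data, the tubular injury median on log2 CPM went from −0.19 to −0.14 and the camera adjusted p was 0.0431. The matrix, mesangial and smooth muscle lists passed without wild-type library 0 too with the preset correlation, while 0 lists passed there with an estimated one (smallest camera adjusted p = 0.692).

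**Figure D2:**
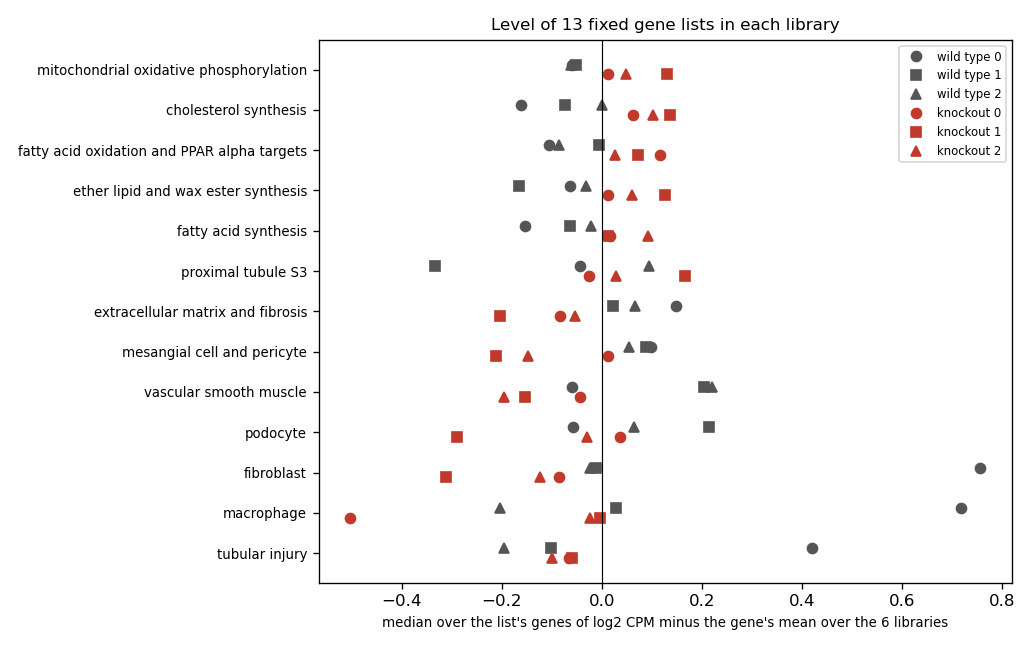
Median level of 13 gene lists in each library, as log2 CPM minus each gene's mean over the 6 libraries, grey for wild type and red for knockout. The 3 knockout libraries lie to the right of the wild-type libraries for oxidative phosphorylation and to the left for the matrix list, and wild-type library 0 lies far to the right for the fibroblast (0.76), macrophage (0.72) and tubular injury (0.42) lists.

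Of the other lists that passed with the preset correlation, proximal tubule S3 genes were higher for 14 of 15 members (median 0.13, camera adjusted p = 0.0102; adjusted p = 0.574 with an estimated correlation). Drug metabolism and glutathione genes were higher for 20 of 27 (median 0.093, adjusted p = 0.0177; adjusted p = 0.574 with an estimated correlation), although Cyp27b1, a member, was the lower gene named above. Androgen-responsive kidney genes were higher for 16 of 19 (median 0.14, adjusted p = 0.0290; adjusted p = 0.584 with an estimated correlation), and distal convoluted tubule genes for 7 of 12 (median 0.13, adjusted p = 0.0478; adjusted p = 0.675 with an estimated correlation). The proximal S3, drug metabolism and androgen calls were lost without wild-type library 1 (medians 0.050, 0.052 and 0.028; camera adjusted p = 0.181, 0.249 and 0.616) and without knockout library 1 (medians 0.099, 0.096 and 0.13; adjusted p = 0.105, 0.0669 and 0.0949). The drug metabolism call was also lost without knockout library 0 (median 0.090, adjusted p = 0.126), the androgen call without knockout library 2 (0.086, adjusted p = 0.139), and the distal tubule call without wild-type library 0 or knockout library 0 (0.053 and 0.063; adjusted p = 0.864 and 0.299). The androgen median was 0.23 without wild-type library 0, 0.34 without wild-type library 2 and 0.26 without knockout library 0. The proximal S3 median was 0.21 without wild-type library 2 and 0.19 without knockout library 0, and the drug metabolism median 0.17 without wild-type library 0. With the length and GC trend taken out, chosen after seeing the data, the drug metabolism and androgen calls were also lost (medians 0.091 and 0.18, camera adjusted p = 0.143 for both). Heat shock and chaperone genes were higher for 17 of 20 (median 0.15, adjusted p = 0.00652; adjusted p = 0.574 with an estimated correlation) and lost their call without wild-type library 0 or 1 or knockout library 1 (medians 0.14, 0.092 and 0.048; adjusted p = 0.0534, 0.0695 and 0.0889). Adipose tissue genes were higher for 11 of 12 (median 0.46, adjusted p = 0.00265; adjusted p = 0.574 with an estimated correlation). Car3 and Fabp4 passed when adjusted over that list alone, and without knockout library 2 the median was 0.15 (adjusted p = 0.124) and without wild-type library 2 it was 0.73.

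The remaining 20 lists did not pass camera. Platelet-activating factor metabolism had a median of −0.044 (adjusted p = 0.935), although Lpcat3, a lysophospholipid acyltransferase, was at 0.22 ± 0.063 (SE) without overlap between groups. The medians were 0.10 for proximal tubule S1 and S2, −0.029 for the thick ascending limb, −0.038 for the thin limb of Henle, −0.069 for principal cells, 0.0029 for intercalated cells and −0.013 for endothelium, with camera adjusted p from 0.113 to 0.825. Immediate early genes had a median of −0.10, circadian clock genes −0.10, interferon response genes −0.056, antigen presentation genes −0.15, ribosomal protein genes 0.045, histone genes −0.30 and nuclear noncoding RNA −0.076. Of the 21 circadian clock genes, 8 were higher and 13 lower in the mean, and 7 had an unadjusted p under 0.05 by edgeR. Over all 14354 genes tested, 1193 did. Changes in opposite directions cancel in a median and in camera, so the clock median does not show that these genes were unchanged. On log2(FPKM + 1) the ribosomal protein list passed (median 0.10, camera adjusted p = 1.69e-06; adjusted p = 0.744 with an estimated correlation on log2 CPM). With 1 library left out, antigen presentation and histone genes passed in 2 of 6 fits. Tubular injury, immediate early, circadian clock and ribosomal protein genes each passed in 1 of 6. Urothelium was at −0.044, B and plasma cells at −0.34, neutrophils at −0.042, erythroid cells at 0.029 and the C57BL/6J against C57BL/6N markers at 0.059. The substrain markers were listed without a direction for each, so their median does not check the substrain. The interferon and platelet-activating factor lists had medians and means below 0 while camera placed them above the other genes, and the intercalated list had a median above 0 and a mean of −0.097. Only 4 adrenal gland genes were expressed enough to be tested, too few for a list test.

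The authors' deposited table lists 88 genes as significant among 13404 tested, 22 higher and 66 lower in knockout. Of the 88, 86 were tested here, and all 86 had the same direction in edgeR, 67 with an unadjusted p under 0.05. DESeq2 called 7 of them. The authors chose these genes from the same libraries, so the shared direction is not independent evidence. The authors' deposited table includes Pdk4 and Scd1 among the higher genes and Cyp27b1, Aldh1a3, Havcr1, Lcn2 and Col1a1 among the lower ones. Of the 64 lower genes tested here, 33 were highest in wild-type library 0, and without that library their median log2 fold change went from −0.73 to −0.58.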

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

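Of 422 values of named genes under other settings, 415 kept their direction and side of the threshold, 5 passed the threshold and 2 reversed. No named gene passed in the main edgeR fit, and many were chosen for a small p or for groups that do not overlap. Keeping both was therefore partly built in and is no sign of robustness. Of 440 list values, 319 kept both, 73 were no longer past the threshold, 11 became so and 37 reversed. The count of genes past the threshold was 0 by edgeR's quasi-likelihood test and 0 to 1 with 1 library left out (1 without wild-type library 2, Snurf, and 1 without knockout library 2). It was 1 with no filter, 1 with robust dispersion, 1 at an adjusted p under 0.10, 1 by limma-voom with library quality weights, 12 by DESeq2 and 47 by DESeq2 without wild-type library 0. DESeq2 without that library, the quality weights and removal of the length and GC trend were chosen after seeing the data. The number of lists past the threshold was 20, ran from 13 to 23 with 1 library left out, and was 0 with an estimated correlation and 0 by fry. The cause was not tested.

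Reversals with 1 library left out are given as ranges of the log2 fold change or list median. Havcr1 ran from −3.79 to 0.19 and Lcn2 from −1.75 to 0.15, both above 0 only without wild-type library 0. List medians ran from −0.16 to 0.069 for platelet-activating factor metabolism, −0.31 to 0.053 for tubular injury, −0.17 to 0.0084 for circadian clock, −0.15 to 0.098 for interferon response and −0.24 to 0.0059 for antigen presentation. They ran from −0.091 to 0.016 for endothelium, −0.16 to 0.051 for thin limb, −0.11 to 0.054 for thick ascending limb, −0.092 to 0.089 for principal cells, −0.073 to 0.051 for intercalated cells and −0.17 to 0.061 for urothelium. For B and plasma cells the range was −0.98 to 0.35, for neutrophils −0.42 to 0.16 and for erythroid cells −0.062 to 0.076. The platelet-activating factor list was at 1.62e-05 on log2(FPKM + 1) and 0.018 without the length and GC trend. The interferon list was at −0.0070 without that trend, nuclear noncoding RNA at 0.032 without it, and the thick ascending limb at 0.033 on log2(FPKM + 1). By fry the platelet-activating factor and interferon medians are those of camera, −0.044 and −0.056, and only the direction of the test differs, down by fry and up by camera. None of these lists passed with all 6 libraries, and the cause was not tested. With 1 library left out the median also changed sign, while camera's direction did not, for the macrophage list (−0.59 to 0.038), which passed with all 6, and for immediate early genes (−0.17 to 0.0094), which did not. On log2(FPKM + 1) the medians of the proliferation, macrophage and T and NK cell lists were −0.092, −0.20 and −0.17, all past the threshold. Without the length and GC trend the macrophage median went from −0.35 on log2 CPM to −0.28, and histone genes passed with the preset correlation (median −0.27, camera adjusted p = 0.0251). With the trend left in, the camera adjusted p of the histone genes was 0.574 with an estimated correlation. Far2 ran from −0.35 to −0.081 over all its alternatives and never passed.

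No paired analysis was possible because the library numbers match no sample label and no label ties a knockout mouse to a wild-type mouse.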

Other observations

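Values of the 2 kidney enzymes that make and degrade active vitamin D lay in opposite directions. Cyp27b1 was called by DESeq2 and not by edgeR, and Cyp24a1 by neither. The authors' Cuffdiff comparison lists both as significant (q = 0.0106 for each). Cyp27b1, which makes the hormone, was at 10.1, 15.9 and 13.9 CPM in the wild-type libraries and at 6.55, 4.72 and 3.77 CPM in knockout (Benjamini-Hochberg adjusted p = 0.429 by edgeR's quasi-likelihood test and 1.99e-06 by DESeq2). Cyp24a1, which degrades it, was at 234, 163 and 191 CPM in wild type and at 301, 380 and 218 CPM in knockout, with overlapping groups (log2 fold change 0.61 ± 0.19 SE, adjusted p = 0.599 by the same edgeR test and 0.878 by DESeq2). Capn11, a calpain protease gene, had 1 fragment in the 3 wild-type libraries together and 13, 29 and 11 in the knockout libraries. The ratio was 57.8 with an exact 95% counting interval of 9.93 to 2324, which covers counting error only.

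Some values set 1 or 2 libraries apart. Ucp1, a gene of brown fat, was at 21.1 CPM in knockout library 2 and at 0.379 to 4.02 CPM in the other 5. Eif2s3y, on the Y chromosome, was at 17.6 and 15.8 CPM in knockout libraries 0 and 1 and at 31.9 to 38.5 CPM in the other 4, while Uty was at 47.5 to 58.1 CPM in all 6.

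Of the tests below, those on the length and GC trend, on wild-type library 0 and on ribosomal RNA, and the interval around each percentage left, were chosen after the results were seen. Small steps shared by whole lists were the main pattern. Gene length and GC content were related to the fold change across genes (Spearman −0.15 and −0.18, across genes, which are not independent replicates). With that trend taken out, the oxidative phosphorylation list kept 112% of its median (95% bootstrap interval over genes 95.8% to 123%), which argues against length or GC of the longest transcripts as its cause. Such an interval treats genes as independent and does not measure the spread between mice. For the matrix list 56.9% was left (26.7% to 81.4%) and for the mesangial list 68.8% (53.2% to 87.6%), so length and GC may account for a large part of the matrix difference. The 10 splits of the 6 libraries are too few for a share under 0.05. The real split passed 20 lists and the others, which mix the genotypes, from 6 to 21, and 2 splits passed 20 or more. For genes by edgeR the real split gave 0 and the highest other 4, and since every split gives at least 0 this tests nothing. By DESeq2 the real split called 12 genes and another split 105, so a split that mixes the genotypes can give more calls. That other split had 936 genes with an unadjusted p under 0.05 by edgeR's quasi-likelihood test, against 1193 for the real split. What set it apart was not tested. An effect of genotype stays open and untested beyond these comparisons.

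Lower injury and immune genes in knockout may come from 1 wild-type mouse or library. The first test of this looked at the 64 genes that the authors' deposited table gives as lower. Without wild-type library 0 their median log2 fold change kept 79.9% of its size, but the authors chose these genes as lower in the same libraries and they are not all injury or immune genes, so this excludes nothing. A second test, added only after the first had given that value, used the fixed lists: without that library the tubular injury median went from −0.22 to 0.053 and the macrophage median from −0.45 to 0.038. For these lists the lower median rests on that library, and whether its mouse had a kidney injury or the sample held other tissue was not tested. Single members can differ from the median. Of the 17 macrophage genes 5, and of the 18 tubular injury genes 0, were lower in every knockout library than in any wild-type library. Of all 14354 genes tested this held for 999.

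Ribosomal RNA left after its removal was lower in the mean in knockout. mt-Rnr1 took 3.54 ± 0.81% of fragments (SD, n = 3) in wild type and 1.90 ± 0.25% in knockout, and Rn45s 0.528 ± 0.147% and 0.340 ± 0.021%. DESeq2 called mt-Rnr1 (adjusted p = 1.39e-06) and not Rn45s (0.709), and edgeR's quasi-likelihood test called neither (adjusted p = 0.599 for both). Less mitochondrial RNA is argued against, since the 13 mitochondrial protein genes took 9.38 ± 0.63% in wild type and 9.33 ± 0.20% in knockout, a difference of −0.051 percentage points. Uneven removal could account for it: Rn45s, made outside mitochondria, was lower too (log2 fold change −0.61, and −0.37 without wild-type library 1, the highest). This explanation also needs both RNAs to vary together. Because both separate by genotype, deviations from the group means on the log2 scale were compared over the 6 libraries, in a single relation. Pearson's r was 0.65 and Spearman's rho 0.60, each with p = 0.417 in an exact two-sided permutation of the 36 pairings within groups, and r was 0.59 without the 2 libraries farthest from the median. The smallest p these pairings can give is 0.0278, so the explanation stays open. Lars2 was at 132, 580 and 273 CPM in wild type and at 134, 134 and 105 CPM in knockout. In the GENCODE transcripts 0 of its stretches of 25 bases occur in mt-Rnr2, which argues against identical fragments of that length shared with mt-Rnr2. Sharing with mt-Rnr1, Rn45s or other ribosomal RNA was not tested.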
